A study of Mus musculus with 6 samples.

How the data were processed

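RNA-seq was measured in 6 libraries of primary mouse motoneuron cultures, 3 from Nmd+/+ and 3 from Nmd-/- animals of a strain given as CD-1. Nmd-/- mice carry the neuromuscular degeneration allele of Ighmbp2, a helicase gene. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a Lexogen mRNA kit. No label says whether replicates of a genotype came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical in part. The markers of sex given below show that the replicates of a genotype did not all come from the same animal.

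The deposited values are FPKM per gene, 1 table per library, made by the authors with Cufflinks per the file headers. The submitters' processing notes name FastQC 0.10.1, Trim Galore 0.4.0, cutadapt 1.8, SAMtools 1.3 and Cufflinks 2.2.1, and the build GRCm38. The version of the aligner, the annotation release, and whether strand was used in quantification are not given in the sources used here. Reads of overlapping and antisense genes may therefore not have been told apart. Each table held 39174 genes with an FPKM, the bounds of its 95% interval and a status. The FPKM of a library are relative to its own total, and no scaling between libraries was stated. Loci in the files start from 0: adding 1 to the start gave the start in the GENCODE M21 annotation for 77.8% of 37604 matched genes, against 1.09% without it. Coordinates are printed from 1.

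FPKM tables carry no counts. Between 39.9% and 41.3% of the low values of a library corresponded to a whole number of fragments within 0.02, so counts were not recovered for most genes. The width of the Cufflinks intervals served as a measure of depth: the fragments that would give such intervals by counting error summed to between 15382006 and 23072449 per library. For Ighmbp2 they came to between 83.6 and 208 fragments per library, and for Actb to between 2322 and 2945.

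All values were computed in R 4.3.3. The main comparison, Nmd-/- minus Nmd+/+, used limma 3.58.1 with an intensity trend on log2(FPKM + 1), with no rescaling between libraries and genotype as the only term. Genes entered with a mean of at least 1 FPKM over the 6 libraries and an accepted Cufflinks status in each, which left 14611. A failed status in at least 1 library removed 35 genes, among them Rps10 and Cacna2d1. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and tests are two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Ratios of mean FPKM are given without the pseudocount. For Ighmbp2, Actb and Igf2bp1 an exact permutation test of the 3 against 3 values was run as well, whose smallest possible p is 0.1.

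Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01. Of the 37 lists, 34 had at least 5 tested members. The lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Ighmbp2, Actb and Igf2bp1; then up to 12 genes per direction with the largest change among those past adjusted p 0.05 with groups that did not overlap; where fewer passed, the genes with the smallest unadjusted p, given as values that did not pass; and from each list the 3 members with the smallest unadjusted p and the member with the highest mean FPKM. Single cell type markers printed as levels came from the lists but were chosen after their values were seen.

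Both genotypes carry replicate numbers 1 to 3. The deviations of same-numbered libraries from their group means correlated across genes at 0.82, 0.70 and 0.39 for the numbers 1, 2 and 3, and each library correlated best with its own number. The pairing comes from these values and not from a label. A fit with the replicate number as a block was an alternative, and its value stands beside a result where it changed the call or moved a count.

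The other alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, sample quality weights, the Xist level as a covariate, no intensity trend, leaving out each library, camera with an estimated correlation, and fry. Leaving out replicate 2 of both genotypes, alone or with the block, and the block together with an estimated correlation, with fry or with median-of-ratios scaling were chosen after seeing the data.

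The procedure was tested on simulated data of 14611 genes with 200 changed, 100 per fold size, for the same comparison of 3 with 3 libraries. Without the block it recovered 48% of 2-fold and 91% of 4-fold changes, with 8 false calls. With the block it recovered 70% and 93%, with 4 false calls. Without the block the median estimate of the 2-fold changes was 1.008 on the log2 scale. The simulated changes were thus not understated, as those of low genes are in the main comparison. Recovery was not measured by level, so these shares need not hold for genes as low as Ighmbp2 and Igf2bp1. Of 200 simulated lists without a shift, 4 were called without the block and 5 with it at an unadjusted p under 0.05. The simulated noise was independent between genes, and without the block same-numbered libraries did not deviate together. The simulation therefore does not measure how often the list test makes false calls where the genes of a list are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.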

Results

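The transcriptome of primary motoneuron cultures was profiled in 3 Nmd+/+ and 3 Nmd-/- libraries, as FPKM per gene. Between 14474 and 14645 genes reached 1 FPKM in each library, and the summed FPKM lay between 664628 and 693258. The depth, read from the width of the Cufflinks intervals, was equivalent to between 15382006 and 23072449 fragments. Intervals cover estimation error within a library only.

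The RNA of all 6 libraries carried low levels of Chat, Mnx1, Isl1 and Prph and high levels of transcripts of other spinal cells. Chat, which encodes the enzyme that makes acetylcholine, did not exceed 0.0692 FPKM in any library, and the motoneuron homeobox gene Mnx1 did not exceed 0.0247 FPKM. Isl1 lay between 0.608 and 1.81 FPKM, and the peripherin gene Prph between 0.128 and 0.284 FPKM. Of the 20 motoneuron markers in the files, however, 11 reached a mean of 1 FPKM, among them Gfra1 (between 8.76 and 16.6 FPKM), Nefh (between 4.85 and 11.7 FPKM) and Slit2 (between 153.6 and 239.1 FPKM). Gad1, which encodes an enzyme of GABA synthesis, lay between 46.9 and 117 FPKM, the glycine transporter gene Slc6a5 between 18.1 and 32.3 FPKM, and the interneuron gene Pax2 between 8.72 and 25.4 FPKM. Among radial glia and astrocyte genes, Vim lay between 2380 and 4452 FPKM, Fabp7 between 283 and 564 FPKM, and Pax6 between 45.7 and 71.4 FPKM. The proliferation marker Mki67 lay between 58.3 and 92.9 FPKM. Whether the RNA came mainly from motoneurons or from other cells of the preparation is not settled by the labels. Chat and Mnx1 near 0 in all 6 libraries, beside the levels of Gad1, Vim and Mki67, argue against motoneurons as its main source. That 11 of 20 motoneuron markers reached 1 FPKM does not decide the question, since markers of other cells did so too. Such counts were 19 of 20 for astrocytes and radial glia, 15 of 21 for other spinal neurons and 6 of 17 for sensory neurons. Each level below, those of Ighmbp2, Actb and Igf2bp1 included, is that of the culture as sequenced.

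Replicate 2 of each genotype stood apart by transcripts of fibroblasts. Col1a1, a collagen gene, measured 38.3 FPKM in Nmd+/+ replicate 2 and 51.1 FPKM in Nmd-/- replicate 2, and no more than 1.36 FPKM (Nmd-/- replicate 1) in the other 4 libraries. Postn measured 47.0 and 44.7 FPKM in these libraries and at most 0.926 FPKM (Nmd+/+ replicate 3) elsewhere.

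**Figure D1:**
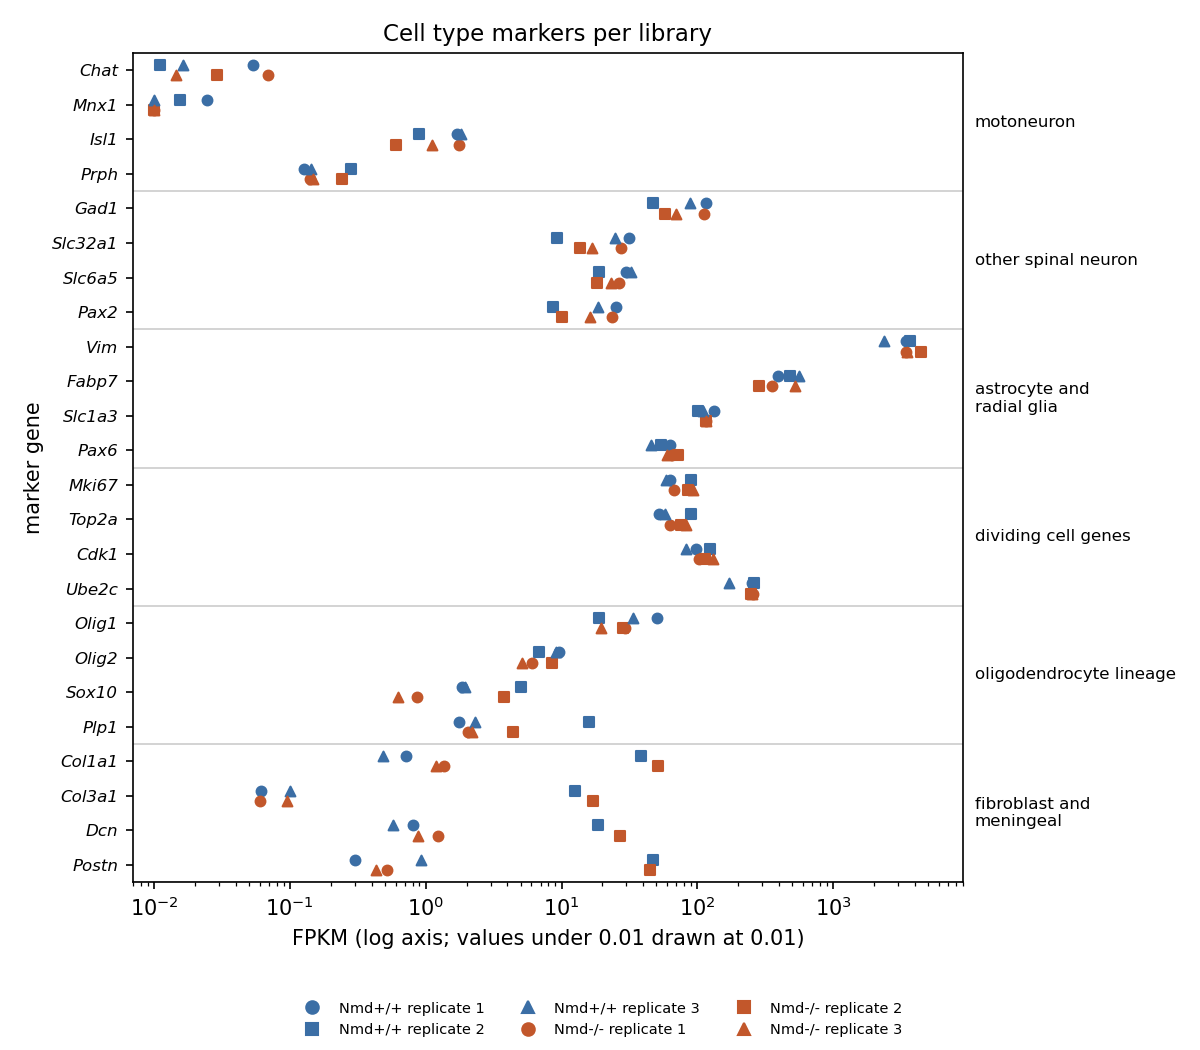
FPKM per library (log axis) of 4 markers from each of 6 cell type lists, with Nmd+/+ libraries in blue, Nmd-/- libraries in orange and the replicate number as the shape of the point. Chat stays at or below 0.0692 FPKM in all 6 libraries while Gad1 lies between 46.9 and 117 FPKM, and Col1a1 is high in replicate 2 of both genotypes (38.3 and 51.1 FPKM).

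The libraries were ordered by replicate number more than by genotype. The first principal component of the tested genes held 61.6% of the variance and placed replicate 1 of both genotypes at one end and replicate 2 of both at the other. Nmd+/+ replicate 1 and Nmd-/- replicate 1 were the closest libraries of all (Pearson r = 0.996 across genes, which are not independent replicates). Of their genes, 23.2% differed by more than the error of the intervals, against 54.5% to 74.6% for every other pair of libraries.

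**Figure D2:**
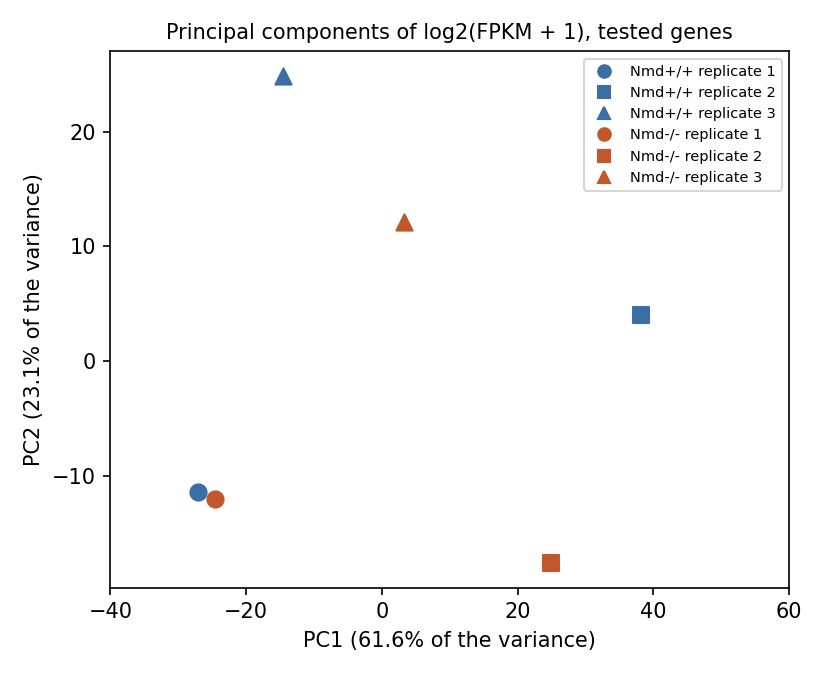
First and second principal components (61.6% and 23.1% of the variance) of log2(FPKM + 1) over the tested genes, with 1 point per library, Nmd+/+ in blue, Nmd-/- in orange and the replicate number as the shape. The points of replicate 1 lie side by side, and the genotypes do not separate along either axis.

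The embryos' sex, which the labels do not give, was spread over both genotypes. Xist, the RNA of the inactive X chromosome, lay between 224.5 and 272.6 FPKM in 4 libraries. In the remaining 2, Nmd+/+ replicate 2 and Nmd-/- replicate 3, it measured 0.155 and 0.143 FPKM. The Y-linked gene Eif2s3y measured 21.2 and 19.6 FPKM in those libraries and 0 in the other 4. Within each genotype the replicates thus did not all come from the same embryo. The libraries numbered 2 differed in sex between genotypes, as did those numbered 3, in the opposite direction.

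The targeted gene was examined first, as a check of the genotype labels. Ighmbp2 (ENSMUSG00000024831, chromosome 19, 3260924 to 3283017, GRCm38) was lower in Nmd-/-, at 0.754 ± 0.142 FPKM (SD, n = 3) against 1.28 ± 0.17 FPKM (SD, n = 3) in Nmd+/+, a ratio of 0.590. The Nmd-/- library was lower in each of the 3 replicate pairs, and every Nmd-/- value lay below every Nmd+/+ value. The log2 difference was -0.38 (SE 0.14, 95% interval -0.70 to -0.05), with adjusted p = 0.9997 in limma over all genes and 0.944 with the replicate block. The exact two-sided permutation test gave p = 0.1, the smallest it can give here. The nmd allele alters splicing of Ighmbp2, so gene-level FPKM need not report the loss of the normal transcript.

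The study's title concerns local translation of β-actin mRNA, so the level of that mRNA in the cultures was compared. Actb (ENSMUSG00000029580, chromosome 5, 142903115 to 142906754) measured 1250 ± 184 FPKM (SD, n = 3) in Nmd+/+ and 1333 ± 103 FPKM (SD, n = 3) in Nmd-/-. The log2 difference of 0.10 (SE 0.17, 95% interval -0.29 to 0.49) was within the spread between replicates (exact permutation p = 0.6). The Nmd-/- value was higher in 3 of 3 pairs, by 0.003, 0.09 and 0.21 on the log2 scale, with adjusted p = 0.999 in limma with the replicate block (SE 0.10). It turned to -0.02 without Nmd+/+ replicate 3. Igf2bp1 (ENSMUSG00000013415, chromosome 11, 95957163 to 96005940), which encodes the zipcode binding protein of β-actin mRNA, measured 1.24 ± 0.59 FPKM (SD, n = 3) in Nmd+/+ and 1.26 ± 0.31 FPKM (SD, n = 3) in Nmd-/-. Its log2 difference was 0.04 (SE 0.22, 95% interval -0.48 to 0.57; exact permutation p = 1), and it was -0.18 without Nmd+/+ replicate 3 and -0.06 without Nmd-/- replicate 2. These values are levels in whole cultures and do not measure RNA in axons or its translation.

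**Figure D3:**
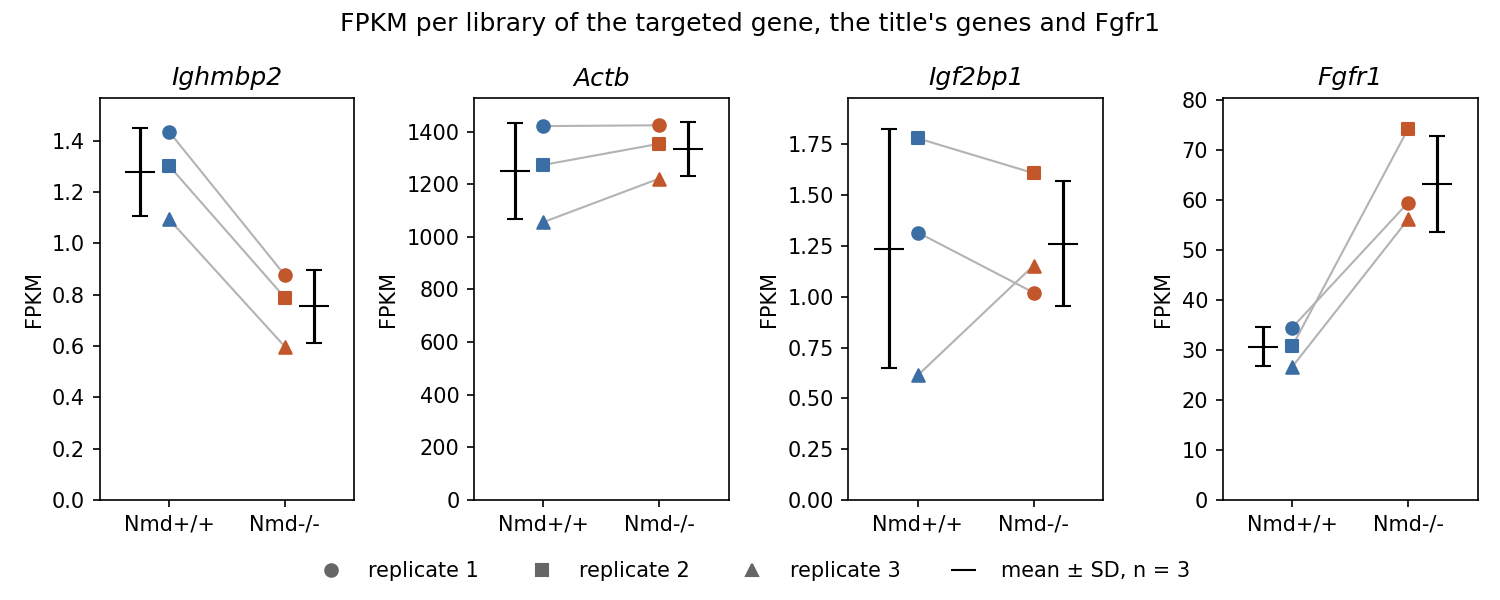
FPKM per library (linear axes from 0) of Ighmbp2, Actb, Igf2bp1 and Fgfr1 in Nmd+/+ (blue) and Nmd-/- (orange), with grey lines joining libraries of the same replicate number and black bars for the mean ± SD (n = 3). Ighmbp2 is lower in all 3 pairs (ratio of means 0.590), Fgfr1 is higher in all 3 pairs (ratio 2.07), and Actb and Igf2bp1 overlap between genotypes.

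Across the transcriptome no gene passed the test between genotypes. Of 14611 genes, 0 had a limma adjusted p under 0.05, and 65 had an unadjusted p under 0.05 (40 higher and 25 lower in Nmd-/-), where chance gives about 731. With the replicate block 0 passed as well, the smallest adjusted p was 0.074, and 711 genes had an unadjusted p under 0.05 (457 higher, 254 lower). The 3 values of each genotype did not overlap for 390 genes, or 2.67%. Chance gives 10% for exchangeable libraries, and less where same-numbered libraries deviate together, as they did here. The ratio of means was at least 2-fold in 19 genes, 5 of them without overlap. The median SE of a log2 difference was 0.17, and 0.12 with the block.

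The gene with the smallest p was Fgfr1 (ENSMUSG00000031565, chromosome 8, 25513654 to 25575714), a receptor for fibroblast growth factors. It measured 30.6 ± 3.9 FPKM (SD, n = 3) in Nmd+/+ and 63.2 ± 9.6 FPKM (SD, n = 3) in Nmd-/-, a ratio of 2.07, and was higher in 3 of 3 pairs. Its log2 difference was 1.02 (SE 0.16) with adjusted p = 0.9997 in limma, and adjusted p = 0.074 with the replicate block. It passed when adjusted over the list alone, as 1 of 23 neurotrophic receptors and ligands. The other 11 genes that the naming rule gave as higher did not pass either. They were Gm17035, Dhrs3, which encodes a retinal reductase, Lsp1, Llgl2, Ttll9, Me3, the growth factor gene Bmp6, 9930013L23Rik, Gm13350, the mitotic gene Cenpf and HOTAIRM1_5. Their log2 differences lay between 0.37 (Gm13350) and 0.75 (Gm17035), and each was higher in 3 of 3 pairs. Bmp6, for example, measured 9.07 ± 1.91 and 13.7 ± 2.3 FPKM (SD, n = 3 each). Among the 12 lower genes were Ighmbp2 and the potassium channel gene Kcna1. Sparcl1, an astrocyte matrix gene, measured 57.3 ± 18.6 FPKM in Nmd+/+ and 34.5 ± 6.2 FPKM in Nmd-/-, and Efnb3, a ligand of Eph receptors, 20.7 ± 4.5 and 14.02 ± 1.16 FPKM (SD, n = 3 each). Gm15726, Ccdc3, D7Ertd443e, Ccl28, Gng13, Rnase1, Foxa1 and Cmtm5 completed the set, with log2 differences from -0.75 (Gm15726) to -0.38 (Ighmbp2). Of these 12, Foxa1 was lower in 2 of 3 pairs and the rest in 3 of 3. Gm17035 and Gm15726 are antisense transcripts, whose reads may not have been separated from those of overlapping genes.

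The gene lists asked whether genes of a cell type or process moved together. Of all tested genes 56.0% were higher in Nmd-/-, and 49.9% with median-of-ratios scaling. The counts of higher and lower members below are to be read against the first share. At the preset correlation 8 of 34 lists passed, 3 toward higher and 5 toward lower values in Nmd-/-. With an estimated correlation 0 passed, and each of the 8 had adjusted p = 0.855 with an estimated correlation. The estimates for these 8 lay between 0.26 (p53 pathway and apoptosis) and 0.87 (other spinal neuron markers), above the preset of 0.01. All 8 passed with the replicate block at the preset correlation, and each had adjusted p = 0.757 with the block and an estimated correlation. Over all genes 0 members of any list passed.

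Dividing cell genes were higher in Nmd-/-, 21 of 22 by their means (camera adjusted p = 4.83e-07; 0.855 with an estimated correlation), with a median log2 difference of 0.19. The difference lay mainly in replicate pair 3, with a median of 0.60 there against 0.07 in pair 1 and -0.07 in pair 2. Cenpf measured 35.4 ± 3.7 and 46.1 ± 2.4 FPKM (SD, n = 3 each), and the mitotic kinase gene Plk1 18.1 ± 5.8 and 22.9 ± 2.1 FPKM. Replication-dependent histones, made in S phase, were higher for 20 of 22 (adjusted p = 0.000629; 0.855 with an estimated correlation), with pair medians of -0.23, 0.45 and 0.30. Their mRNAs mostly lack poly(A) tails, so their levels in an mRNA library also depend on the preparation. Genes of the p53 pathway and apoptosis were higher for 25 of 30 (adjusted p = 0.0123; 0.855 with an estimated correlation), with pair medians of 0.01, 0.08 and 0.28. The members with the smallest p, however, included Rrm2b at 7.65 ± 0.91 and 6.09 ± 1.12 FPKM, lower in Nmd-/-, and Gtse1, itself a gene of dividing cells, at 15.6 ± 4.7 and 19.6 ± 0.4 FPKM. The histone call ended without Nmd+/+ replicate 2 (adjusted p = 0.916) and at a mean of at least 5 FPKM (0.0713). It also ended with replicate 2 of both genotypes left out, where the direction turned (camera adjusted p = 0.914). The p53 call ended without Nmd+/+ replicate 1 (0.389), Nmd+/+ replicate 3 (0.461), Nmd-/- replicate 2 (0.748) or Nmd-/- replicate 3 (0.0536), and with no filter on low values (0.0516).

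Presynaptic genes were lower for 35 of 41 (camera adjusted p = 0.000388; 0.855 with an estimated correlation), with a median of -0.12 overall and pair medians of -0.04, 0.08 and -0.37. The synaptobrevin gene Vamp2 measured 363 ± 108 and 339 ± 104 FPKM, and the calcium channel subunit gene Cacnb4 5.08 ± 1.09 and 4.07 ± 0.82 FPKM (SD, n = 3 each). Voltage-gated ion channels were lower for 25 of 34 (adjusted p = 0.0187; 0.855 with an estimated correlation), with pair medians of -0.03, 0.10 and -0.29. Kcna1 measured 1.94 ± 0.29 and 1.23 ± 0.22 FPKM. Markers of other spinal neurons were lower for 12 of 15 (adjusted p = 0.0106; 0.855 with an estimated correlation), with pair medians of -0.10, 0.09 and -0.35. Slc17a6, the vesicular glutamate transporter gene, measured 28.8 ± 9.1 and 22.8 ± 5.4 FPKM, and Gad1 83.8 ± 35.0 and 79.6 ± 28.4 FPKM. In pair 2 these 3 lists had the opposite sign. Without Nmd+/+ replicate 1, Nmd+/+ replicate 3 or Nmd-/- replicate 2 the calls ended, with adjusted p of 0.623, 0.857 and 0.955 for presynaptic genes, 0.867, 0.491 and 0.730 for ion channels, and 0.817, 0.857 and 0.730 for other spinal neurons. The ion channel call also ended without Nmd-/- replicate 3 (0.0592), with no filter (0.153) and at a mean of at least 5 FPKM (0.144), as did that of other spinal neurons at a mean of at least 5 FPKM (0.1003).

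Markers of the oligodendrocyte lineage were lower for 9 of 10 (camera adjusted p = 0.00472; 0.855 with an estimated correlation), with pair medians of -0.29, 0.05 and -0.54. Olig2 measured 8.51 ± 1.48 and 6.55 ± 1.75 FPKM, and Sox10 2.945 ± 1.804 and 1.75 ± 1.76 FPKM (SD, n = 3 each). Under the block Pdgfra and Sox10 passed when adjusted over the list alone. The list's call ended without Nmd+/+ replicate 1 (0.0544), Nmd+/+ replicate 2 (0.242), Nmd-/- replicate 1 (0.0851) or Nmd-/- replicate 3 (0.298).

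Mitochondrially encoded genes were lower for all 15 tested, by their means and in each of the 3 pairs (camera adjusted p = 9.13e-05; 0.855 with an estimated correlation). The median log2 difference was -0.17, with pair medians of -0.04, -0.27 and -0.21. The cytochrome oxidase gene mt-Co1 measured 26197 ± 4196 and 23556 ± 2838 FPKM (SD, n = 3 each). These genes took 26.6% of the summed FPKM in Nmd+/+ replicate 3, the highest share, and 19.2% in Nmd-/- replicate 2, the lowest. The call ended without Nmd+/+ replicate 3 (adjusted p = 0.654), Nmd-/- replicate 1 (0.0522), Nmd-/- replicate 2 (0.0717) or replicate 2 of both genotypes (0.0604), with quantile normalization (0.0614) and with no filter on low values (0.239). Nuclear genes of oxidative phosphorylation were lower for 44 of 74 and did not pass (adjusted p = 0.0530), but passed with the block (adjusted p = 0.0425; 0.757 with the block and an estimated correlation). They also passed as lower with median-of-ratios scaling, at a mean of at least 5 FPKM and with sample quality weights. The same held without Nmd+/+ replicate 2 or without Nmd-/- replicate 1.

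**Figure D4:**
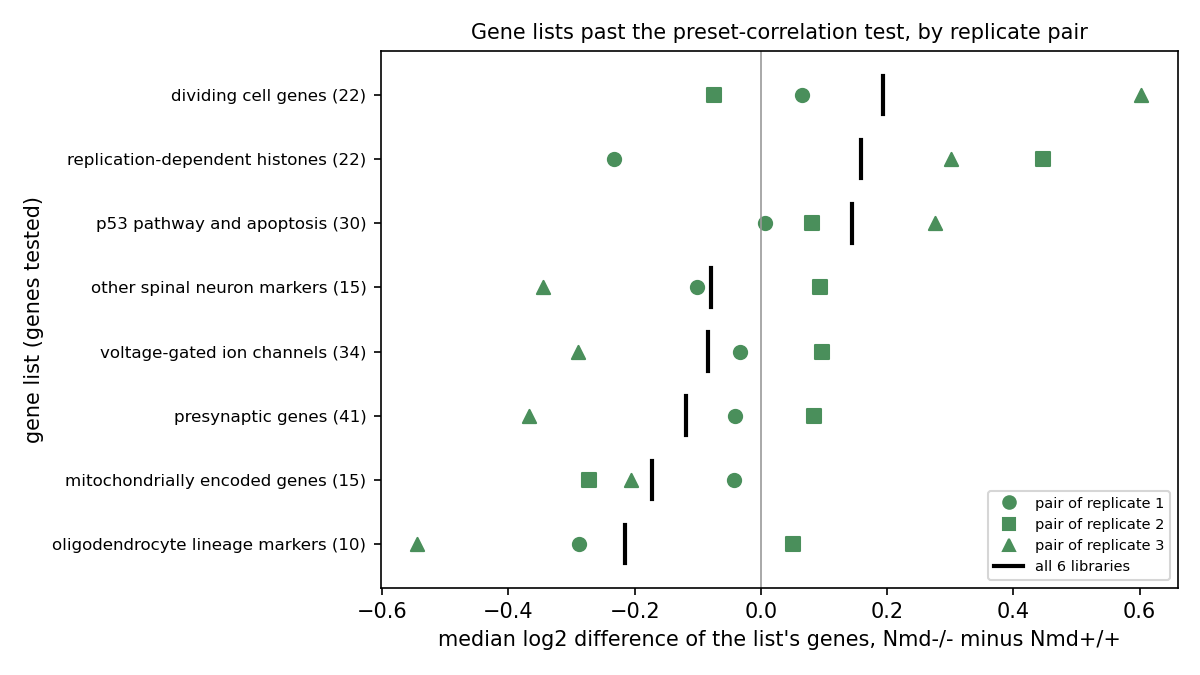
Median log2 difference (Nmd-/- minus Nmd+/+) of the genes in each of the 8 lists past the preset-correlation test, within each replicate pair (green points, shape by replicate number) and over all 6 libraries (black line). Only the mitochondrially encoded genes and the p53 pathway have the same sign in all 3 pairs, and the dividing cell genes reach 0.60 in pair 3 against -0.07 in pair 2.

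The lists closest to the study's question were not among these 8. Proteins that bind β-actin mRNA or carry RNA along axons were higher for 18 of 33 (camera adjusted p = 0.507), and their median (0.01) differed in sign from their mean (-0.01) and their camera direction. Fmr1 measured 16.6 ± 3.1 and 14.3 ± 2.0 FPKM, and Hnrnpr 91.5 ± 5.7 and 84.4 ± 6.8 FPKM (SD, n = 3 each). Actin cytoskeleton genes were higher for 29 of 47 (adjusted p = 0.318), factors associated with Ighmbp2 for 12 of 14 (0.0530), and genes of spinal muscular atrophy and motoneuron disease for 25 of 42 (0.748). Translation factors were higher for 35 of 51 (0.492), with Eef1a1 at 2686 ± 378 and 2891 ± 157 FPKM, aminoacyl-tRNA synthetases for 9 of 23 (0.513), ribosome biogenesis factors for 27 of 35 (0.0869) and nonsense-mediated decay factors for 15 of 25 (0.439). Cytosolic ribosomal proteins were higher for 62 of 81 (0.0740) and passed with the block (adjusted p = 0.0425; 0.758 with the block and an estimated correlation), with Rps2 at 189 ± 32 and 220 ± 28 FPKM. With the block and median-of-ratios scaling they did not pass.

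Among the other cell type lists, motoneuron markers were lower for 9 of 11 tested (camera adjusted p = 0.0606; 0.0425 with the block), with Gfra1 at 14.1 ± 3.5 and 11.8 ± 2.8 FPKM (SD, n = 3 each). The motoneuron marker with the smallest p, Slit2, was higher in Nmd-/-, at 179 ± 42 and 216 ± 28 FPKM. Schwann cell and neural crest markers were lower for 7 of 9 (0.0606; 0.0120 with the block), and fibroblast and meningeal markers higher for 16 of 19 (0.520; 0.000437 with the block). For these 3 lists adjusted p = 0.757 with the block and an estimated correlation. None of the 3 passed with the block and replicate 2 of both genotypes left out. Motoneuron markers also did not pass with the block and median-of-ratios scaling. They did pass as lower with sample quality weights and, without the block, with replicate 2 of both genotypes left out. Like every other list, they did not pass with an estimated correlation or in fry. Under the block Sox10 passed when adjusted over the Schwann list alone, and Col1a1 and Loxl1 over the fibroblast list alone. Sensory neuron markers were higher for 3 of 6 (0.621), astrocyte and radial glia markers for 8 of 19 (0.318), and microglia markers for 4 of 5 (0.520). Endothelial and skeletal muscle markers had 3 tested members each and erythroid markers 0, so these lists were not tested.

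Among the remaining processes, axon growth genes were lower for 31 of 43 (camera adjusted p = 0.0606; 0.00764 with the block) and neurofilament and microtubule genes for 22 of 34 (0.0985; 0.0132 with the block). Both had adjusted p = 0.757 with the block and an estimated correlation. Nefl measured 52.7 ± 18.3 and 40.5 ± 12.2 FPKM, and Basp1 484 ± 100 and 439 ± 81 FPKM (SD, n = 3 each). Neurotrophic receptors and ligands were higher for 16 of 23 (0.207), the unfolded protein and integrated stress response for 27 of 39 (0.837), immediate early genes for 14 of 23 (0.741), cholesterol synthesis genes for 15 of 23 (0.298), glycolysis and hypoxia genes for 17 of 31 (0.513), interferon-stimulated genes for 12 of 13 (0.0659) and heat shock proteins for 13 of 20 (0.696). The interferon list passed as higher with sample quality weights, with the block and median-of-ratios scaling, and without Nmd+/+ replicate 2, Nmd-/- replicate 1 or Nmd-/- replicate 3. Small nuclear and nucleolar RNAs were higher for 4 of 5 (0.492), and their median (0.05) and mean (0.01) differed in sign from their camera direction. Snora73a of that list passed under the block when adjusted over the list alone.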

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

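The count of 0 genes held in every alternative except the replicate block with replicate 2 of both genotypes left out, which was chosen after seeing the data, leaves 1 residual degree of freedom and gave 20 genes. There Fgfr1 (adjusted p = 0.0110), Ccdc3 (0.0134), Efnb3 (0.0307) and Foxa1 (0.0457) passed. The replicate block changed no call other than those printed beside the lists above. The 65 genes at an unadjusted p under 0.05 became 711 with the block, 695 with the block and median-of-ratios scaling, 977 with sample quality weights, 517 with no filter, 29 at a mean of at least 5 FPKM, 250 with replicate 2 of both genotypes left out and 1487 with the block as well, and between 20 (Nmd+/+ replicate 3) and 473 (Nmd+/+ replicate 2) without single libraries. Leaving out single libraries gave log2 differences for Ighmbp2 from -0.44 to -0.31 in the 4 settings in which its mean stayed at or above 1 FPKM, for Actb from -0.016 (Nmd+/+ replicate 3) to 0.20 and for Igf2bp1 from -0.18 (Nmd+/+ replicate 3; -0.06 without Nmd-/- replicate 2) to 0.22. Sample quality weights gave 0.26 for Igf2bp1 and 0.16 for Actb, and a pseudocount of 0.1 gave -0.70 for Ighmbp2. The other settings lay between -0.40 and -0.38 for Ighmbp2, 0.08 and 0.11 for Actb, and 0.02 and 0.11 for Igf2bp1.

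The count of 8 lists became 15 with the replicate block, 14 with the block and median-of-ratios scaling, 17 with sample quality weights, 5 at a mean of at least 5 FPKM, 13 with replicate 2 of both genotypes left out and 17 with the block as well. It became 0 with an estimated correlation or fry, each with or without the block. Leaving out single libraries gave between 3 lists (Nmd+/+ replicate 1) and 17 (Nmd+/+ replicate 2), with 6 without Nmd+/+ replicate 3, 13 without Nmd-/- replicate 1, 5 without Nmd-/- replicate 2 and 6 without Nmd-/- replicate 3. The direction turned, with no call, for other spinal neuron markers without Nmd-/- replicate 2 (adjusted p = 0.730), presynaptic genes without Nmd+/+ replicate 3 (0.857) or Nmd-/- replicate 2 (0.955), voltage-gated channels without the same libraries (0.491 and 0.730), and histones with replicate 2 of both genotypes left out (0.914; 0.983 with the block). Over the single libraries left out, adjusted p ran from 1.53e-08 to 0.857 for other spinal neuron markers, from 1.03e-14 to 0.955 for presynaptic genes and from 1.69e-09 to 0.867 for voltage-gated channels. These fits had no block, so leaving out 1 library left its replicate number in 1 genotype only. Part of these changes, and of those of the 3 lists below, can therefore come from differences between replicate numbers. How large that part is was not tested. 3 lists outside the 8 passed in opposite directions: aminoacyl-tRNA synthetases higher without Nmd+/+ replicate 2 and lower without Nmd+/+ replicate 3, the unfolded protein and integrated stress response likewise and lower without Nmd-/- replicate 2, and fibroblast markers higher without Nmd+/+ replicate 2 or Nmd-/- replicate 1 and lower without Nmd-/- replicate 2. Of the other lists close to the study's question, all higher in Nmd-/-, factors associated with Ighmbp2 passed with sample quality weights, translation factors with these weights and without Nmd+/+ replicate 2, ribosome biogenesis factors in those settings and with replicate 2 of both genotypes left out, and ribosomal proteins in these 3, without Nmd-/- replicate 1 and with quantile normalization. Actin cytoskeleton genes passed without Nmd+/+ replicate 2 and with replicate 2 of both genotypes left out. In the latter with the block, actin, translation, ribosomal, ribosome biogenesis, nonsense-mediated decay and stress response lists passed, all higher. The other settings gave between 6 and 9 lists.

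Depth limits the low genes: Ighmbp2 rests on 83.6 to 208 fragments' worth of interval per library, and 24535 genes lay below a mean of 1 FPKM.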

Other observations

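The tests of a single library, of the neuron share in replicate pair 3, of cell types in pair 1 and of the intervals of Fgfr1 were chosen only after the results were seen, as were the genes named in the next 2 paragraphs other than Gm15726. For the tests of Fgf target genes and of chromosome 19 the bounds were set beforehand, and the spread a value had to exceed was settled after the values were seen.

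4 transcripts of the pseudoautosomal region, which the X and Y chromosomes share, were lower in Nmd-/- in 3 of 3 pairs. Erdr1 (Y, 90784738 to 90816464) measured 189 ± 134 FPKM in Nmd+/+ and 70.3 ± 24.3 FPKM in Nmd-/-, and Gm21887 (X, 170009659 to 170019281) 214 ± 153 and 78.6 ± 28.6 FPKM (SD, n = 3 each). Gm15726 (X, 169979047 to 169985232) measured 2.06 ± 0.36 and 0.840 ± 0.437 FPKM, and Gm21742 (Y, 90843934 to 90844074) 1.961 ± 0.677 and 0.936 ± 0.784 FPKM. The values of Erdr1 and Gm21887 were highest in Nmd+/+ replicate 1, at 344 and 390 FPKM, so the difference was widest in pair 1. These transcripts have near-identical copies, so how reads were shared between them is uncertain, and the grouping by region was noticed in the data and not tested. None passed in limma with all 6 libraries (adjusted p = 0.9997 each, and 0.730, 0.850, 0.475 and 0.850 with the replicate block). Erdr1 and Gm21887 were among the 20 genes that passed with the block and replicate 2 of both genotypes left out.

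With the replicate block, 3 of the 12 genes of smallest p were among those the naming rule gave. Some of the others make or bind extracellular matrix, a grouping also noticed in the data and not tested. The proteoglycan gene Vcan was lower in 3 of 3 pairs, at 11.03 ± 6.49 FPKM in Nmd+/+ and 6.92 ± 4.07 FPKM in Nmd-/- (SD, n = 3 each), and the integrin gene Itga3 higher in 3 of 3, at 16.7 ± 5.4 and 24.7 ± 7.1 FPKM. Mgp, the matrix Gla protein gene, was also higher in 3 of 3 pairs, with most of its transcript in replicate 2, at 32.3 FPKM in Nmd+/+ and 48.1 FPKM in Nmd-/-. Their limma adjusted p with the block lay between 0.506 and 0.850.

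The 8 lists past the preset-correlation test form the first pattern. If Nmd+/+ replicate 3 alone made them, leaving out other libraries would keep more calls. Of the 8, 3 were kept without it, and the fewest kept without another library was also 3. These fits had no block, so leaving out any library left the replicate numbers unequal between genotypes. That can end calls whichever library made them, so the test cannot decide and this explanation stays open. Pair 2 showed no decrease of presynaptic genes, of which 29 of 41 were higher in Nmd-/-. In pair 3, where the presynaptic median was -0.37, a lower neuron share that raised every other cell type alike is argued against, since the lower quartile of dividing cell genes (0.508) lay 0.106 above the upper quartile of astrocyte genes (0.402). A higher share of dividing cells in that pair, with or without a lower share of neurons, was not tested, and these quartiles do not speak against it. An effect of the genotype stays open, since the outcome of its test depended on how the correlation between genes was treated: each of the 8 lists passed at the preset correlation, and none with an estimated correlation (adjusted p = 0.855 each) or in fry. The estimates, from 0.26 to 0.87, all lay above the preset of 0.01, so the preset p-values of these lists are likely too small. With 6 libraries there are 10 splits, too few for a share under 0.05: 6 splits, the real one included, gave at least 8 lists, the highest other gave 20, and of the 3 others that part all 3 pairs 1 gave 15 and the rest 7 each.

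For genes, the real count was 0, which each of the 10 splits reaches by construction, so the comparison says nothing about chance. The highest other split gave 929. That split set Nmd+/+ replicates 1 and 3 and Nmd-/- replicate 1 against the rest, which points to a structure of the samples other than genotype.

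The higher Fgfr1 in Nmd-/- is the second pattern. Estimation error is argued against, since the Cufflinks intervals overlapped in 0 of the 9 comparisons of a Nmd+/+ with a Nmd-/- library, as is a gain of the chromosome 8 segment, since 21 tested genes within 1 Mb had a median log2 difference of -0.0124 and a maximum of 0.33. A cell type more common in the Nmd-/- culture is argued against for pair 1 only, the pair whose libraries were the closest of all. There Fgfr1 differed by 0.77, and no cell type list with at least 5 tested members had a median above 0.0658. In pair 3 the dividing cell genes had a median of 0.60. For pairs 2 and 3 such a source of the higher Fgfr1 RNA was not tested and stays open. Whether the RNA goes with more Fgf signalling stays open: 14 target genes fixed before this test had a median of -0.0094 with the block, 7 of them higher, which met the bound set beforehand against it by less than their spread. An effect of the Ighmbp2 genotype on Fgfr1 stays open: with these 6 libraries the comparison of genotypes over all genes gave an adjusted p of 0.9997, and 0.074 with the replicate block.

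A chromosome 19 segment carried along with the nmd allele was looked for as a source of differences near Ighmbp2. Of 199 tested genes within 10 Mb, 9 (4.52%) had an unadjusted p under 0.05 with the block, against 4.86% of other genes (Fisher's exact test, two-sided, p = 1). The share met the bound set beforehand against such a segment by less than its counting error, and a segment without effect on expression would not be seen, so the question stays open.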
